A study of Mus musculus with 4 samples.

How the data were processed

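RNA-seq was made from retinal microglia collected by fluorescence-activated sorting on EYFP, with 200 cells per library and full-length cDNA of the SMART-seq kind amplified by PCR, per the labels' protocols. The deposited table, made by the authors, holds 1 FPKM value (fragments scaled to transcript length and to the mapped fragments of the library) per gene and library, rounded to 2 decimals. The genome build was mm10, per the submitters' processing notes. The aligner, the quantifier and the gene annotation are not given in the sources used here. FPKM do not keep read counts, so depth per library is unknown and no counting interval could be given; without molecular identifiers, PCR copies cannot be told from separate molecules. In a look at the low values, made after the other results were seen, 206 to 427 genes per pair of libraries lay between 0.1 and 1 FPKM in both. Their most common ratio between the libraries was 0.91 to 1.04, as steps of 1 read in libraries of similar depth would give, but only 8.7% to 17% of the ratios lay near it, so relative depth was not taken from it. The 4 columns were matched to the 4 samples by their titles. Of the 15586 gene identifiers, 15470 were in a GRCm38.p6 gene table, from which coordinates were taken, and 116 were not.

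From the FPKM, log2(FPKM + 1) was computed for the 7823 genes with a mean of at least 1 FPKM over the 4 libraries. Fold changes on this scale understate the change of low genes. Knockout was compared with control by limma's moderated test (limma 3.58.1 in R 4.3.3, trended prior variance, 2 residual and 3.99 prior degrees of freedom), with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 31 gene lists, holding 725 genes of which 644 were in the table, the 24 with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, and with an estimated correlation and fry as alternatives. Figures were drawn with matplotlib 3.10.9.

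Camera used the same trended variance as the gene test. The written design did not state this in words, although the alternatives fixed with it included an untrended variance for each list. Both versions had been run and their counts seen, 13 lists with the trend and 11 without, before the trended one was settled as the main version, and both are given.

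The test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule had 4 parts: Map3k7 and its binding partners; the 12 genes in each direction with the largest change past the threshold and no overlap of groups, filled up with the smallest p where fewer passed; up to 4 members per list with the smallest p; and, for other cell types and RNA quality, up to 3 members with the highest mean. Symbols that are only identifiers were not named, and some genes the rule names are not reported here. Other genes named below or in the results were chosen after their values were seen, and were Polr2a, Rps2, P2ry12, Cx3cr1, Cd74, Apoe, Ccnb2, Birc5, Set, Srsf2, Cox7c, H2az1, Ccl12, Mgl2, Ms4a4c, Aif1, Clec4a3, Ms4a6d, Tmem176a, Rpgrip1, Eif2s3y, Uty and Ddx3y.

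Alternatives were pseudocounts of 0.1, 0.5 and 5 FPKM, no filter or a mean of at least 5 FPKM, rescaling to the same sum, median ratio scaling, quantile normalization, an untrended or robust variance, the replicate number as a block, each library left out, an adjusted p under 0.1 and a 2-fold minimum. A mean of at least 100 FPKM was added after the data were seen. The code was tested on simulated data with the measured spread and 50 genes changed at each size. The changed genes were drawn from the higher-expressed ones only. Noise was normal on the log2 scale, and simulated FPKM below 0 were set to 0, which shrank some of the largest changes. It called 2% of genes changed 4-fold, 14% at 16-fold, 40% at 64-fold and 62% at 256-fold, with 2 false calls among 7798 genes. These rates hold for that setting, which did not copy the many single-library values of the data.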

Results

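RNA was profiled from microglia, the resident immune cells of the retina, sorted from 2-month-old mice. The mice carried a tamoxifen-inducible Cre recombinase at the Cx3cr1 locus and floxed alleles of the gene for TAK1, a kinase that links cytokine and innate immune receptors to NF-kB and MAP kinase signalling. Libraries of 200 sorted cells each were made for 2 groups of 2. Control mice received corn oil for 5 days, and TAK1 knockout mice received tamoxifen at 75 mg/kg for 5 days. The series title places the work in retinitis pigmentosa, an inherited loss of photoreceptors, but the labels of these 4 samples name no disease genotype. Only the knockout group received tamoxifen, so the deletion and the drug cannot be separated. The genotype label of both knockout samples reads Tak3 where the protocol reads Tak1, and the groups are named here as the titles give them. Nothing in the labels says that the libraries came from separate animals, so every p-value measures only the spread between these samples, which may be technical.

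Values were FPKM for 15586 genes, and the number of reads per library was unknown. FPKM summed to 969700 and 863652 in control 1 and 2 and to 823229 and 812009 in knockout 1 and 2. Genes at 1 FPKM or more numbered 4481 and 3777 in the controls against 6055 and 5628 in the knockouts, whereas genes at 100 FPKM or more numbered 1176, 1220, 1243 and 1243. Genes at 0 FPKM numbered 5833 and 5537 in the controls and 6035 and 4507 in the knockouts, with no order by group. Many genes were near 0 in 1 library and high in another: in 2514 of the 7823 genes tested (32.1%), a single library held over 90% of the summed FPKM. Values near 0 also occurred in genes used by every cell. Polr2a, the large subunit of RNA polymerase II, read 0.01 and 0 FPKM in the controls and 8.50 and 9.04 in the knockouts, and Rps2 read 0.60 in control 1 and 106 in control 2. A value near 0 therefore does not show that a gene was silent, and values per library are given for such genes. Across the tested genes, Pearson's r on the log2 scale was 0.59 between the controls, 0.52 between the knockouts and 0.51 to 0.54 across groups; genes are not independent replicates.

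The targeted gene, Map3k7 (chromosome 4, 31963492 to 32023470, GRCm38.p6), which encodes TAK1, read 0.03 and 0 FPKM in the controls and 0.02 and 0.08 in the knockouts. It was at the floor in both groups, was not tested, and could not check the labels. Among its binding partners, Tab2 read 20.4 and 0.62 FPKM in the controls and 24.4 and 28.3 in the knockouts, and Tab3 read 0, 0.02, 0.02 and 4.49 in the same order. Neither Tab2 nor Tab3 passed the test (limma adjusted p = 0.698 and 0.709), and Tab1 was not analysed here. Of 20 tested TAK1 signalling partners, 9 lay above both controls in both knockouts and 0 below. Of all 7823 tested genes, 2174 lay above and 890 below. The list did not pass (camera adjusted p = 0.248). Otulin, a deubiquitinase of linear ubiquitin chains, read 0.05 and 0.39 FPKM in the controls and 34.3 and 65.3 in the knockouts.

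The comparison of knockout with control asked which transcripts differed in microglia after deletion of TAK1. Lyz2, which encodes lysozyme, read 12053 ± 3997 FPKM (SD, n = 2) in controls and 2189 ± 417 (SD, n = 2) in knockouts. Wfdc17, a secreted myeloid protein gene, read 5555 ± 1072 and 894 ± 138 FPKM, and Ms4a7, a macrophage membrane protein gene (chromosome 19, 11321039 to 11336146, GRCm38.p6), read 1580.3 ± 47.6 and 172 ± 23.6 FPKM (SD, n = 2 each). The cytokine gene Il1b read 513 ± 176 and 30.7 ± 8.38 FPKM, and B2m, the light chain of MHC class I, read 11987 ± 1084 and 7445 ± 368 FPKM (SD, n = 2 each). Actb, cytoplasmic actin, read 15021 ± 1984 and 5005 ± 2544 FPKM (SD, n = 2 each). Ccr2, the chemokine receptor of inflammatory monocytes, read 316 and 151 FPKM in the controls and 1.81 and 0.59 in the knockouts. Cd209a, a lectin of monocyte-derived dendritic cells, read 503 and 886 FPKM against 1.19 and 2.10, and Clec12a read 144 and 199 FPKM against 0.36 and 0.48. Gemin6, S100a11 and Fkbp7 had the same form, with 112 to 249 FPKM in the controls and under 1 FPKM in the knockouts.

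In the other direction, the lysosomal protease gene Lgmn read 1438 ± 125 FPKM in controls and 3872 ± 830 in knockouts, and the tetraspanin gene Cd81 read 794 ± 44.6 and 4330.3 ± 2492 FPKM (SD, n = 2 each). Pdc, which encodes the rod protein phosducin, read 844 ± 132 FPKM in controls and 2646 ± 266 in knockouts (SD, n = 2 each). The other 8 genes named in this direction, Sult1a1, Isca2, Pdhb, Tmx1, Mrpl39, Slc25a17, Arl6ip5 and Rab9, all read under 1 FPKM in both controls and 106 to 328 FPKM in both knockouts.

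**Figure D1:**
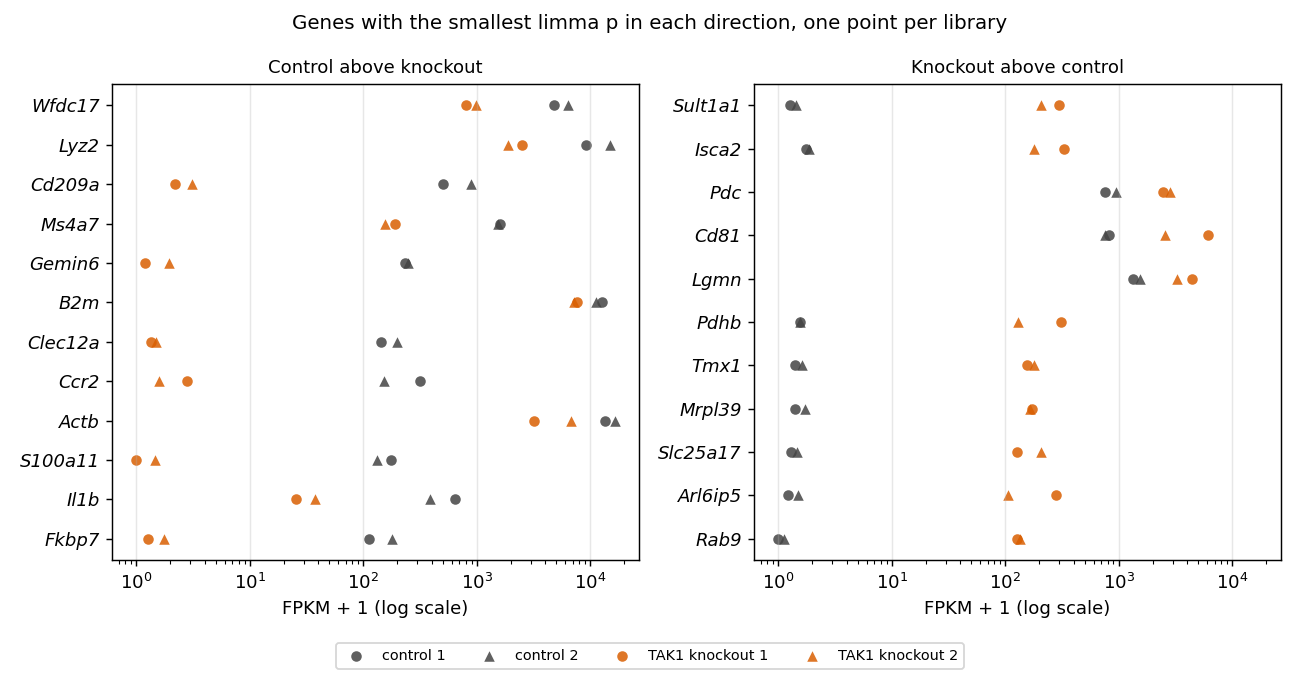
FPKM plus 1, on a log axis, of genes with the smallest limma p in each direction among genes whose groups did not overlap, 12 on the left and 11 on the right. Each point is 1 library, with controls in grey, knockouts in orange, circles for replicate 1 and triangles for replicate 2. None of the 23 genes passed the adjusted test, and 8 of the 11 on the right read under 1 FPKM in both controls.

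None of these genes passed limma's moderated test after Benjamini-Hochberg adjustment (smallest adjusted p = 0.547): 0 genes were called higher and 0 lower. At an unadjusted p under 0.05 there were 602 genes, 475 higher and 127 lower, where chance gives 391. Quantile normalization called 2 higher, among them Cd81, and 3 lower, Lyz2, Wfdc17 and Ccl12; the last was named after its values were seen. Without knockout 1 the test called 697 higher and 4 lower, and without knockout 2 it called 1306 higher and 5 lower. All of the 697, and 1303 of the 1306, read under 1 FPKM in both controls. The lower genes were Cd74, Ms4a7, Apoe and H2-Ab1 in the first fit and Ms4a7, Set, Srsf2, Cox7c and H2az1 in the second. Without either control the test called 0 genes. In these fits the lone knockout library is assumed to vary like the controls. The groups did not overlap in 2174 genes above and 890 below the controls, together 39.2% of tested genes where chance gives 33.3%. With 2 against 2, an exact two-sided permutation test cannot go below p = 0.333.

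The median log2 fold change of all tested genes was 0.94 on the log2(FPKM + 1) scale, knockout minus control. The list medians below are on that scale, with 0.94 not subtracted unless given as relative to all genes, whereas camera compares each list with the other genes. That shift was 1.35 for genes with a mean of 1 to 20 FPKM, 0.78 for 20 to 100 FPKM and -0.11 for 100 FPKM or more. Median ratio scaling left a shift of 0.32 and quantile normalization 0.12. The share of higher genes among those with an unadjusted p under 0.05 was 78.9%, against 42.7% after median ratio scaling, 60.1% after quantile normalization and 39.8% among genes at a mean of 100 FPKM or more, a filter added after the data were seen.

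Of 24 fixed lists with enough tested members, 13 passed camera with a preset inter-gene correlation of 0.01, 6 higher and 7 lower in knockouts than other genes. None of the 13 passed with an estimated correlation or with fry, which tests whether a list's genes move one way without comparing them with other genes. With an estimated correlation camera tests on the residual degrees of freedom, here 2, so a list could hardly pass. For ribosomal proteins the estimate, -0.0161, was below the preset value, yet camera's adjusted p rose from 5.51e-11 to 0.32. The loss of calls there therefore does not show that correlation between genes made them. With camera's variance left untrended, 11 of the 24 passed. Cytosolic ribosomal proteins was the 1 list of the 13 that also passed in each of the 4 fits that left out a library.

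Ribosomal protein transcripts were lower in the knockouts. Of 50 tested, 32 lay below both controls in both knockouts and 0 above, with a median of -1.585 log2 units relative to that of all genes (camera adjusted p = 5.51e-11; adjusted p = 0.32 with an estimated correlation). Their own median was -0.65, against 0.94 for all genes and -0.11 for those at 100 FPKM or more. Relative to all genes they stood at -0.56 after quantile normalization (adjusted p = 0.00379) and at -0.55 among genes at a mean of 100 FPKM or more (0.000174). Rps25 read 5358 ± 1937 FPKM in controls and 2180.2 ± 440 in knockouts, and Rpl35 read 8266 ± 2016 and 4588 ± 44.9 (SD, n = 2 each). The 50 genes took 4.78% and 6.51% of the summed FPKM in the controls and 3.88% and 3.89% in the knockouts. No ribosomal gene passed alone, adjusted over the list alone or over all genes.

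Markers of monocytes, cells that a Cx3cr1 reporter can also label, stood higher in the controls as a list. All 8 tested monocyte markers lay below the all-gene median, but only 2 lay below both controls in both knockouts, and 0 above. The list median was -2.46 (camera adjusted p = 0.000716, or 0.415 with an estimated correlation). The call was lost without knockout 2, although the median there was -2.38, and without control 2 fewer than 5 members were left to test. Without control 1 the median was -4.57. Ccr2 was lower adjusted over the list alone (adjusted p = 0.0222), while Plac8 read 0.13 and 173 FPKM and S100a6 0 and 118 FPKM in control 1 and 2. Among 10 perivascular macrophage markers, Ms4a7 and Clec12a were lower adjusted over the list alone (adjusted p = 0.00592 and 0.0136). The list passed (camera adjusted p = 0.0298; adjusted p = 0.444 with an estimated correlation), but not without control 1 (0.397) or knockout 1 (0.701), where its median turned from -0.83 to 2.64 in both cases (-3.25 without control 2, -3.32 without knockout 2), nor after median ratio scaling (0.11). Pf4 read 367, 1.04, 0.51 and 303 FPKM in control 1, control 2, knockout 1 and knockout 2, with no order by group.

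Rod photoreceptor transcripts stood higher in the knockouts. Of 20 tested, 16 lay above both controls in both knockouts and 0 below, with a median of 1.96 (camera adjusted p = 1.31e-05; adjusted p = 0.415 with an estimated correlation). Relative to all genes the list stood at 1.02, at 0.77 after median ratio scaling, 1.69 after quantile normalization and 1.87 among genes at a mean of 100 FPKM or more. The call was lost without knockout 2 (adjusted p = 0.217), where the median was 1.92. Pdc and Pde6g were higher adjusted over the list alone (adjusted p = 0.0426 and 0.047). Pde6g, a subunit of the rod phosphodiesterase, read 80.2 ± 5.82 FPKM in controls and 616 ± 18.8 in knockouts (SD, n = 2 each). The 8 bipolar cell markers (median 2.08) and the 7 amacrine and ganglion cell markers (median 2.73) also passed, with camera adjusted p = 0.0306 and 0.0491. With an estimated correlation the adjusted p was 0.415 for both. Pcp2 of bipolar cells read 3.28 and 95.7 FPKM in the controls and 647 and 572 in the knockouts. The bipolar call was lost without control 1 (0.223), knockout 1 (0.123) or knockout 2 (0.0758), where the medians were 1.78, 3.55 and 3.33. The amacrine and ganglion call was lost in all 4 fits that left out a library, with medians of 2.18 to 3.39. It was also lost after median ratio scaling (camera adjusted p = 0.0523). There the list stood at 1.94 relative to all genes, against 1.79 in the main fit.

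Cone markers did not pass as a list (camera adjusted p = 0.891). Adjusted over the list alone, 3 of 8 passed at adjusted p = 0.045 and went both ways. Opn1mw and Gnat2 read under 1 FPKM in both controls and 28.4 to 272 FPKM in the knockouts, while Gngt2, also expressed by myeloid cells, read 1669 ± 166 FPKM in controls and 739 ± 98.7 in knockouts (SD, n = 2 each). Müller glia and astrocyte markers did not pass (camera adjusted p = 0.891, lower, though their median of 1.30 lay above that of all genes; higher after quantile normalization, 0.671), and their median was -0.46 without control 2. Too few members were tested for endothelial (2), pericyte and smooth muscle (2), neutrophil (2), retinal pigment epithelium (1), lymphocyte (1) and red blood cell (0) markers. Among these, the pericyte marker Vtn, at 0.12 and 0.16 FPKM in the controls and 96.1 and 29.3 in the knockouts, passed adjusted over the list alone (adjusted p = 0.0274). Mitochondrially encoded transcripts were not analysed here.

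Antigen presentation genes were lower in the knockouts as a list of 21 (median -0.73; camera adjusted p = 0.00583; adjusted p = 0.415 with an estimated correlation). Of the 21, 7 lay below both controls in both knockouts and 4 above. Several MHC class II genes were lower, to different extents in the knockouts. H2-Ab1 read 3512 and 4428 FPKM in the controls, 1222 in knockout 1 and 102 in knockout 2. Cd74, the class II invariant chain, read 12697 and 17767 against 6244 and 181. H2-Oa, also of class II, went the other way, at 0 and 0.08 FPKM against 51.3 and 14.7. Relative to all genes the list stood at -1.67, at -0.94 after quantile normalization and at -0.62 among genes at a mean of 100 FPKM or more. It was lost without control 1 (0.078), control 2 (0.124) or knockout 2 (0.0561), and its median was -0.47 without control 1 and -1.11 without control 2. Type I interferon response genes gave a median of -0.80 over 28 (camera adjusted p = 0.0107; adjusted p = 0.415 with an estimated correlation), lost without control 2 (0.284) or knockout 2 (0.0561). Their median was -1.66 without control 1 and -0.24 without control 2. Ifitm3 read 2648 and 1815 FPKM in the controls and 820 and 161 in the knockouts, and Rtp4 read 833 ± 137 and 227 ± 65.3 (SD, n = 2 each), while Irf9, a subunit of the interferon-activated transcription factor, read 1.42 and 0.41 against 47.5 and 120. Monocyte markers were lower in the same libraries (median -2.46).

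Inflammasome and cell death genes gave a median of -0.71 over 21 (camera adjusted p = 0.0288; adjusted p = 0.415 with an estimated correlation). Il18 read 236 and 38.4 FPKM in the controls and 3.10 and 1.98 in the knockouts, and Casp1 read 541 ± 82.6 and 185 ± 133 (SD, n = 2 each). The call was lost in each fit that left out a library (0.0949 to 0.217), and the median was 0.65 without control 1 and -1.08 without knockout 2. Monocyte markers were lower in the same libraries (median -2.46). NF-kB target genes did not pass (camera adjusted p = 0.0906), with a median of -0.40 and a mean of -0.04 over 30 genes; the median was 0.64 without control 1, 0.22 without control 2 and -0.08 without knockout 2. Members went both ways: Il1b stood higher in the controls, whereas Tnf read 0 and 0.04 FPKM in the controls and 80.1 and 43.4 in the knockouts. AP-1 and immediate-early genes did not pass (camera adjusted p = 0.26, lower, with a median of 0.24) but did without control 2 (0.0386), where the median was -0.80; it was -0.21 without knockout 1. Atf3 read 45.5 and 57.6 FPKM in the controls and 0.07 and 0.22 in the knockouts.

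Homeostatic microglia genes passed as higher (camera adjusted p = 0.0306; adjusted p = 0.438 with an estimated correlation), although their median of 0.92 was 0.018 below that of all genes. Of 33 tested, 15 lay above both controls and 2 below, where of all 7823 tested genes 2174 lay above and 890 below. P2ry12 read 569 and 790 FPKM in the controls and 1794 and 830 in the knockouts, Selplg read 34.7 ± 5.83 and 339 ± 141 (SD, n = 2 each), and Cx3cr1 read 101, 88.9, 88.2 and 73. The 37 lysosomal genes also passed (camera adjusted p = 0.0204; adjusted p = 0.438 with an estimated correlation), with a median of 0.98, 18 members above both controls and 0 below. Lgmn was higher adjusted over the list alone (adjusted p = 0.0433). Both passed after quantile normalization (0.00586 and 9.21e-05), with medians 0.643 and 0.955 above that of all genes, and at a mean of 100 FPKM or more (0.000266 and 0.000524). Neither list passed with an untrended variance (0.321 and 0.276), after median ratio scaling (0.845 and 0.949), where both medians lay 0.223 below that of all genes, or in any fit that left out a library (0.0848 to 0.919 and 0.0545 to 0.479). Without knockout 1 camera's direction for the homeostatic list was lower (0.919), with a median of 0.53. Rod markers were higher in the same libraries (median 1.96).

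Disease-associated microglia genes did not pass as a list (camera adjusted p = 0.734, lower, with a median of 0.48) but did as lower after median ratio scaling (0.0076), while quantile normalization put it on the higher side (0.299). Lyz2 was lower adjusted over the list alone (adjusted p = 0.00405). Apoe read 4904 and 4968 FPKM in the controls and 9190.4 and 1647 in the knockouts. Complement and phagocytosis genes did not pass (camera adjusted p = 0.734, lower, with a median of 0.27; higher after quantile normalization, 0.797). Their members included C1qb, at 1366 ± 751 FPKM in controls and 5568 ± 3425 in knockouts, and Fcgr2b, at 1173 ± 83.5 and 440 ± 48.1 (SD, n = 2 each). TGF-beta signalling did not pass (camera adjusted p = 0.891, lower, with a median of 0.82, or -0.07 without control 2).

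Proliferation genes passed as higher (median 2.35 over 19; camera adjusted p = 0.0224; adjusted p = 0.522 with an estimated correlation). Ccnb2 read 315 FPKM and Birc5 266 FPKM in knockout 2, against under 1 FPKM in each of the other libraries. The call was lost without control 1, control 2 or knockout 2, where the median was 2.49, 2.03 and 2.59, against 3.76 without knockout 1. It was also lost at a mean of at least 5 FPKM (camera adjusted p = 0.0563), with a median of 2.475. Stmn1, which neurons also express, read 44.7 and 1.48 FPKM in the controls and 284 and 729 in the knockouts. Cholesterol synthesis passed as lower (median -0.38 over 18, camera adjusted p = 0.0491, or 0.415 with an estimated correlation). The call was lost without control 1, knockout 1 or knockout 2. It was also lost after median ratio scaling (camera adjusted p = 0.157) and quantile normalization (0.0531). Relative to all genes the list stood at -1.11 and -1.20 after these scalings, against -1.32 in the main fit. Its median was 1.93 without control 1, -2.32 without control 2, -1.34 without knockout 1 and -0.63 without knockout 2. Fdps read 51.1 and 93.2 FPKM in the controls and 0.12 and 0.70 in the knockouts, and Fdft1, of the same pathway, read 0.07 and 0.18 against 15.4 and 40.7. Glycolysis (camera adjusted p = 0.114, higher), cholesterol export and liver X receptor targets (0.775, higher) and nuclear-encoded oxidative phosphorylation (0.114, lower) did not pass. The last had a median of -0.01 (-0.43 to 0.19 with a library left out) and a mean of 0.52, passed as lower after median ratio scaling (0.000132) and without knockout 2 (0.0171), and lay on the higher side after quantile normalization (0.603). Glycolysis passed with no filter (0.0339) and at a mean of 100 FPKM or more (0.0214).

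**Figure D2:**
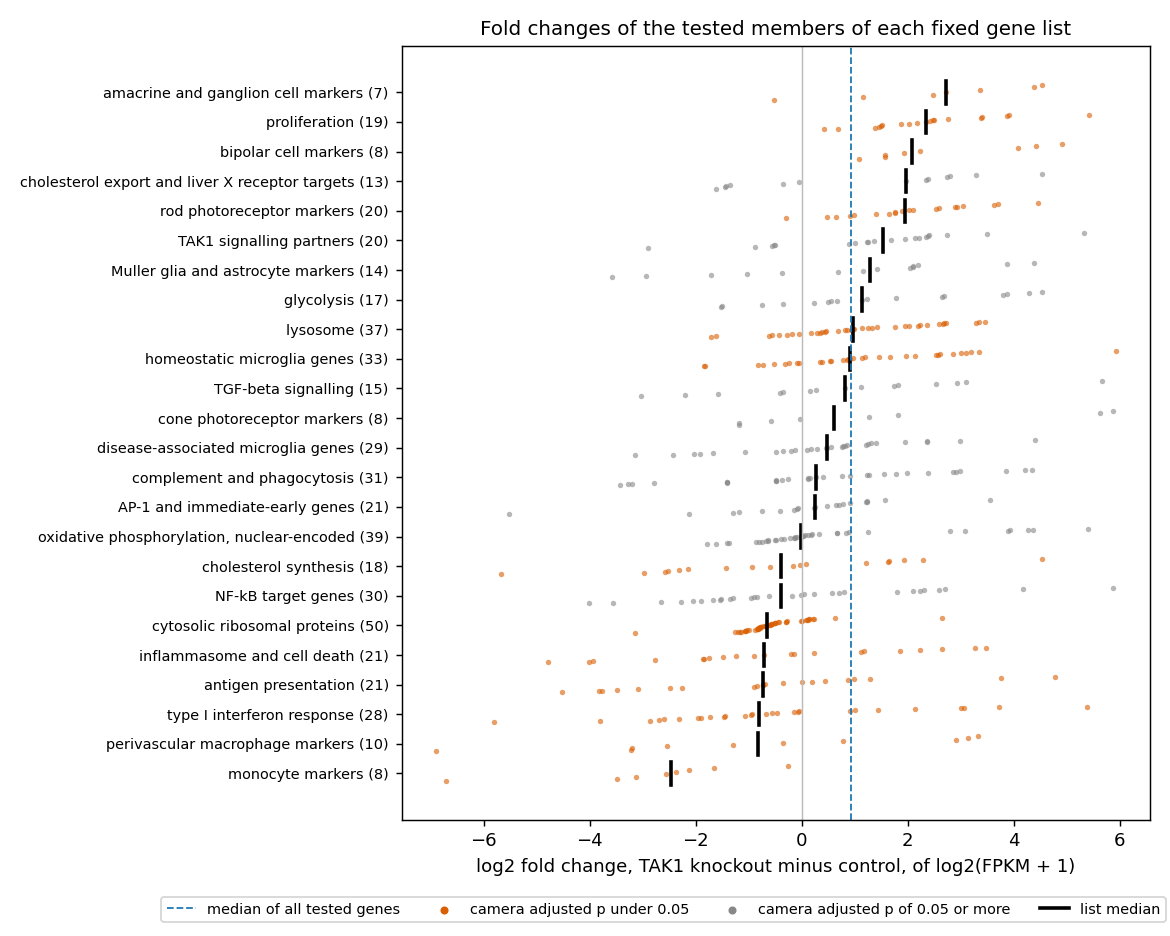
Log2 fold change, knockout minus control on the log2(FPKM + 1) scale, of each tested member of the 24 lists, 1 point per gene, with the number tested in parentheses. Black bars are list medians and the dashed line is the median of all tested genes, 0.94. Orange lists passed camera with the preset correlation and grey lists did not; none passed with an estimated correlation.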

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

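The filter at a mean of 100 FPKM was chosen after the data were seen; the other alternatives were planned. No gene passed in either direction under 3 other pseudocounts, 3 other filters, rescaling to the same sum, median ratio scaling, an untrended or robust variance, an adjusted p under 0.1 or a 2-fold minimum. Quantile normalization called 2 genes higher and 3 lower. The replicate numbers were not taken as pairs. The deviations of same-numbered libraries correlated at 0.017, which gave no sign of pairing. With Pearson's r of only 0.59 between the controls and 0.52 between the knockouts, a shared effect could be missed. With the replicate block, 15 genes were called higher and 20 lower, in a fit with 1 residual degree of freedom whose prior took the spread of each gene wholly from the trend. Leaving out each library gave 0 to 1306 genes higher and 0 to 5 lower, the lone library being assumed to vary like the other group; the cause was not tested. The Map3k7 log2 fold change was 0.048, and 0.366 at a pseudocount of 0.1 FPKM, since all its values lay near 0. It has no value after quantile normalization, where it is filtered out, or under stricter filters.

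Over all lists tested, 7 passed at a mean of at least 5 FPKM, 7 of the 12 of the 13 main lists still tested there. At a mean of at least 100 FPKM 7 passed, 6 of the 7 main lists still tested and glycolysis. With an estimated correlation, tested on 2 residual degrees of freedom, 0 passed, and with fry 0. Leaving out each library gave 3 to 6 lists, of which 2 to 6 were among the 13, and an adjusted p of 0.0848 to 0.919 for the homeostatic microglia list. Other settings gave 10 to 13 lists, of which 8 to 13 were among the 13: 8 after median ratio scaling, 9 with no filter and 11 with an untrended variance. With the replicate block 12 lists passed, 11 of the 13 and NF-kB target genes as lower (adjusted p 0.00581). Leaving aside an estimated correlation, fry and the fits without a library, cholesterol synthesis passed in 3 of 10, amacrine and ganglion markers in 5 of 10, perivascular macrophages in 7 of 10 and inflammasome genes in 8 of 11. For lists, camera has no robust option, so that alternative was not run. Without TAK1 knockout replicate 1 camera's direction for the homeostatic microglia list turned to lower (adjusted p 0.919), while its median stayed above 0 (0.53, against 0.92) and relative to all genes was -0.11 against -0.02; the cause was not tested. Of the 125 named genes tested, S100a4, Nefl, Pf4, Pcna and Cd9 changed sign in at least 1 alternative. None of the 24 named by smallest p among genes whose groups did not overlap did. That choice left only a change of scaling able to turn their sign, so it is little evidence of stability. Cd9 went from 0.75 to -0.13 under median ratio scaling, which also lowered the median of all genes from 0.94 to 0.32. At the measured spread, the simulation recovered 14% of 16-fold changes among higher-expressed genes, so most changes of that size or less could go undetected.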

Other observations

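The added marker lists below were written before the values of their genes were read. The tests of monocytes in both controls, of expression within microglia, of scaling, of the share of the highest genes, of other splits, and of library complexity for the monocyte and rod lists were chosen after the results were seen.

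The chemokine gene Ccl12 read 81986 and 22413 FPKM in the controls and 2287 and 8969 in the knockouts, which was 8.45%, 2.60%, 0.28% and 1.10% of the summed FPKM. Mgl2, a lectin of dendritic cells and macrophages, read 83 and 111 FPKM in the controls and 0 and 0.30 in the knockouts, and Ms4a4c read 417 and 1211 against 138 and 120. Aif1, the gene for the microglia and macrophage protein IBA1, read 2389 and 2318 against 1246 and 1611. Y-linked transcripts differed between libraries of 1 group: Eif2s3y read 0.57 and 328 FPKM in the controls and 84.4 and 1.55 in the knockouts, Uty read 0.05, 85.5, 14.2 and 0.17, and Ddx3y read 47.5, 58.6, 41 and 0.31. None of these genes passed limma's test (adjusted p = 0.559 to 0.943).

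Monocyte genes, taken as a list, and several macrophage genes stood higher in the controls. Further markers of blood-derived macrophages, 25 of 28 tested, none of them in the fixed lists, had a median of -1.798 log2 units relative to that of all genes (list median -0.86, against -0.47 to 1.19 for 95% of 10000 random lists matched on expression), which is what other myeloid cells in the control sort may give. Of the 25, 22 lay below the all-gene median of 0.94 and 3 above. Lying below that median is not the same as being lower in the knockouts. Some of the 22 had a positive log2 fold change, such as Tmem176a at 0.651. Microglia also express several of these genes, and the EYFP gate would keep monocytes and macrophages that express Cx3cr1. The abundant ones moved to different extents. Clec4a3 read 701 and 816 FPKM in the controls and 135 and 154 in the knockouts, while Ms4a6d read 1492 and 1116 against 1105 and 883. Tmem176a read higher in both knockouts, at 203 and 235 against 360 and 327. Lower library complexity alone would leave the further markers within the range of lists matched on expression. They lay below it, at -0.86 against -0.47 to 1.19, which argues against complexity alone for those 25 genes. For the fixed monocyte list it stays open. The fixed monocyte list's median of -2.46 stood at percentile 0 of matched random lists (95% range -0.93 to 2.52). That list was singled out for this same shift, so its rank is no separate evidence, and 2 of its 8 members lay below both controls. Whether classical monocytes were in both controls stays open. Of 7 monocyte genes, 4 were above 10 FPKM in control 2 and 3 in control 1, which is 1 short of the bound set for that test. The rule as first written would have counted this against monocytes in both controls. Lower expression in microglia without TAK1 stays open too, as Ms4a7 (log2 fold change -3.197) was measured in bulk and the group is confounded with tamoxifen.

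Rod transcripts stood higher in the knockouts. Further rod transcripts, 20 of 21 tested and none in the fixed lists, had a median of 1.712 log2 units relative to that of all genes. The list median was 2.65, against -0.34 to 2.48 for 95% of matched random lists (percentile 99). Of the 20, 14 lay above the all-gene median and 6 below. Among the 6, Rpgrip1 read 86.2 and 175 FPKM in the controls and 5.05 and 16.9 in the knockouts. More photoreceptor RNA in the sorted samples could give the list's shift. A sort on EYFP should remove rods, though microglia that engulf them may carry their RNA. Library complexity alone stays open, as the further list lay only just above the matched range and 6 of its 20 members lay below the all-gene median. The fixed rod list stood at percentile 99.95 of matched random lists, but it was singled out for the same shift that this rank measures. Scaling between libraries stays open as part of the rod difference. The fixed list's median was 1.082 after median ratio scaling and 1.815 after quantile normalization. Neither scaling took the rise away. For the first, the bootstrap range over members was 0.648 to 1.878, around the bound of 1. That range covers the choice of genes within the same libraries, not the spread between libraries. The rule as first written would have counted these medians, both above 1, against scaling. Whether the RNA came from free rod material, engulfed rods or the sort was not tested.

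More genes reached 1 FPKM in the knockouts. The median log2 fold change was 1.347 for genes at a mean of 1 to 20 FPKM and -0.11 for those at 100 FPKM or more. A difference in library complexity, such as loss of low transcripts before amplification, could give this. Genes at 0 FPKM did not separate by group, at 5833 and 5537 in the controls and 6035 and 4507 in the knockouts. That count therefore does not show a greater loss in both controls. The test of a few genes taking most of the FPKM gave no decision by itself. The 10 highest genes took 26.1% and 22.2% in the controls and 22.2% and 19.3% in the knockouts. The lowest control and highest knockout differed by 0 percentage points. Yet these 2 libraries, control 2 and knockout 1, had 3777 and 6055 genes at 1 FPKM or more. A larger share for a few genes would also lower the others alike at all levels, whereas the shift was 1.347 for low genes and -0.11 at 100 FPKM or more. These values argue against it as the main cause of the shift. An effect of TAK1 deletion on the number of genes expressed was not tested apart from these.

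The 602 genes at an unadjusted p under 0.05 were the most among the 3 splits of the 4 libraries into 2 and 2 (1 of 3 splits gave as many, the real one), and the highest of the other splits gave 194. So few splits cannot give a share under 0.05.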
